A study of Mus musculus with 6 samples.

How the data were processed

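The samples were 6 RNA preparations from mouse acute myeloid leukemia cells driven by the MLL-AF9 fusion gene, on a C57BL/6 background and enriched for leukemia stem cells, the cells able to maintain the disease. Of these, 3 were controls and 3 had a knockdown of Kdm1a, which encodes the histone lysine demethylase also called LSD1. Per the labels' protocols, cryopreserved cells were thawed, spun with virus-containing medium that held 5% X63 supernatant, and cultured overnight. RNA was taken with a column kit, 40 ng was amplified to sense-strand cDNA, and the fragmented cDNA was labelled with biotin for exon-type arrays with several probe sets per gene. The design text states that the samples came from 2 animals, and no label ties a sample to an animal. The p-values therefore measure the spread between these 6 samples, some of which share an animal, and that spread may be largely technical.

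The authors deposited log2 values in 2 tables, made by robust multi-array averaging (RMA) per the submitters' processing notes. RMA corrects background, equalises the arrays and summarises the probes of each probe set, and its version, the probe set definition and the genome build are not given in the sources used here. The value table holds 267824 probe sets, and 0 of its value columns belonged to no sample. The authors' gene-level table holds 23770 rows with Ensembl identifiers and no symbols, and the reference table used here pairs no Ensembl identifier with a symbol. The platform annotation gave 1 symbol for 242247 probe sets, several for 2077 and none for 23500. Probe sets with several symbols or none entered only the fit over all probe sets. Of the 18957 symbols, 15906 were current in the RefSeq gene table of assembly GRCm38.p6, 3003 were updated through a synonym, 41 had several candidates and 7 were not listed, and both of the last kinds were kept as given. No coordinates are printed, because the build of the deposited values is not given.

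The design fixed before the data were examined assumed that the gene-level table carried symbols and took the brightest row of each gene. With no symbols there, each gene's value was instead the mean of its probe sets, which gave 18916 genes with a median of 10 probe sets. This mean equalled a row of the authors' gene-level table in all 6 arrays, within a distance of 1e-06, for 7324 genes, of which 6414 had over 1 probe set. The median of the probe sets equalled a row for 1623 genes. The brightest probe set and the authors' unnamed gene table became alternatives.

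Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes, threshold 0.05), with the group as the only term and no filter on dim genes. For 30 gene lists fixed before the data were examined, camera with its preset correlation of 0.01 was run over lists with at least 5 measured genes, adjusted over the lists, and camera with an estimated correlation and fry were run beside it. Unequal change among the probe sets of a gene was tested with the F test of limma's diffSplice. The named genes were Kdm1a, the 12 genes with the largest change in each direction among those that passed with all 3 knockdown arrays on the same side of all 3 controls, filled up to 12 by the smallest unadjusted p and then described as not passing, with predicted gene models left out. The rule also took, for each list, up to 4 passing members or else the 2 with the smallest p, and a fixed set of Kdm1a partners and leukemia program genes (Rcor1, Gfi1, Hdac2, Hoxa9, Meis1, Myb and Myc). Hdac1, also in that set, was not analysed here.

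The titles number the samples 1 to 3 in both groups. Deviations from the group means, correlated across genes between the control and the knockdown array of the same number, gave r = 0.625, 0.105 and 0.343. All were above the limit set for treating the numbers as pairs, although control 2 correlated better with knockdown 3, at 0.359, and knockdown 2 with control 3, at 0.17. Only in number 1 did both arrays correlate best with each other, so pairing of numbers 2 and 3 is not shown. Genes are not independent replicates. The fit with the replicate number as a block was therefore an alternative whose value is printed where it changed a call. No array was a copy of another: 0 or 1 of the 18916 gene values was exactly equal, with no tolerance, between any 2 arrays.

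The alternatives left out each array in turn, renormalised by quantiles or array medians, left out dim genes, changed the variance model, weighted the arrays, and changed the gene summary and the thresholds. Added after the data were seen were every alternative for unequal probe sets, the lists without Kdm1a, cyclic loess, the brightest probe set, the authors' gene table, random lists matched on mean expression, estimated correlations within blocked fits, and blocks for the number-1 arrays and for classes of arrays by upper quartile. The steps were tested on simulated data with 200 changed genes among 18916, in 10 simulations of 3 against 3 arrays. The fit recovered 4.4% of genes changed by 0.5 on the log2 scale, 75.6% at 1, 96.4% at 1.5 and 99.2% at 2, and 6.51% of its calls were false. With 200 changed genes the adjusted threshold is easier to pass than where few genes change. The simulated arrays also had no classes and no number-1 difference. These shares therefore do not show that changes of such sizes would have passed in the data. Camera called 1 of 300 unchanged lists. The simulated genes were drawn independently, so this count does not cover lists with correlated members. In the data the estimated correlation was 0.689 for the oxidative phosphorylation list. Signal medians per array ranged from 5.68 to 5.80 over the probe sets, and the number of arrays limits the precision.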

Results

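Gene expression was measured on exon-type arrays in mouse MLL-AF9 acute myeloid leukemia cells enriched for leukemia stem cells, in 3 control samples and 3 samples with a Kdm1a knockdown. Values are log2 signals, and differences are knockdown minus control. The median residual SD of a gene was 0.191 on this scale. The samples came from 2 animals, so some samples share an animal. The comparison asks which transcripts differ after the knockdown of Kdm1a, a demethylase that removes methyl groups from histone H3. This demethylase works with corepressors of the RCOR family and with the GFI transcription factors, which repress genes. The sequences used for the knockdown are not given in the sources used here. Direct effects of these sequences on genes other than Kdm1a were therefore not tested.

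Kdm1a itself fell by 1.96 on the log2 scale (95% interval -2.24 to -1.68), from 8.12 ± 0.0381 in the controls to 6.16 ± 0.133 in the knockdown (SD, n = 3 each; limma adjusted p = 0.0072). By this mean over 23 probe sets, of which 4 had a control mean under 6, the knockdown samples held 25.7% of the control level (interval 21.1 to 31.2), and by the median of the probe sets the log2 difference was -2.56. The values were 8.08, 8.14 and 8.15 in the controls and 6.24, 6.01 and 6.23 in the knockdown. All 19 Kdm1a probe sets with a control mean of at least 6 were lower in every knockdown array than in every control array, with a median difference of -2.16, and so were 20 of all 23. The exact two-sided permutation test of 3 against 3 gave p = 0.1, the smallest it allows. The call was lost when control 2 (0.112), control 3 (0.101), knockdown 2 (0.078) or knockdown 3 (0.0809) was left out (limma adjusted p in parentheses), while the log2 difference stayed between -2.001 and -1.885.

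**Figure D1:**
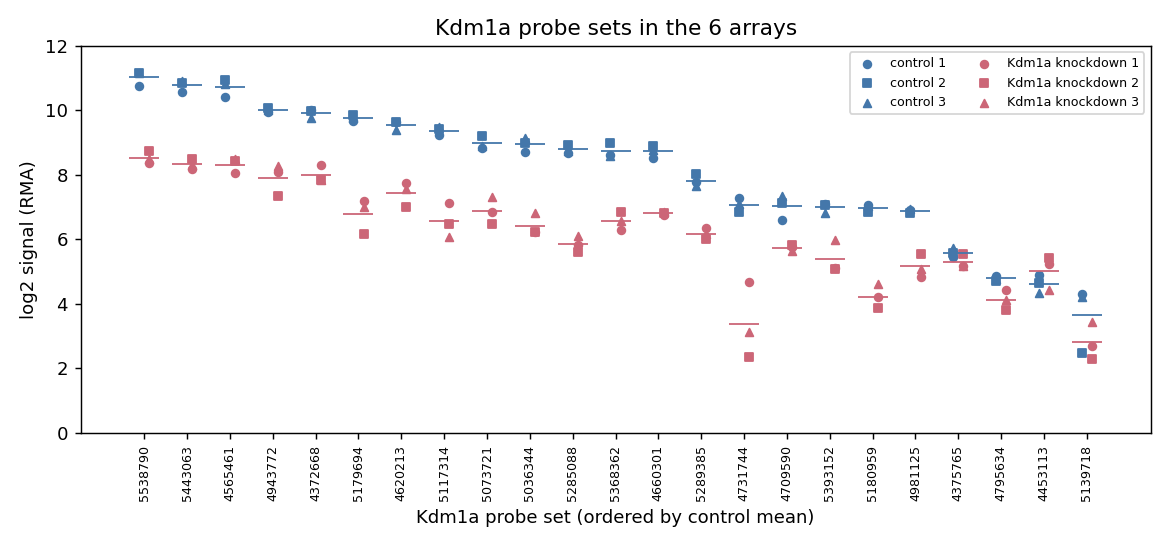
Log2 signal of the 23 Kdm1a probe sets (x axis, ordered by control mean) in the 3 control and 3 knockdown arrays, with points for arrays and lines for group means. In 20 probe sets the knockdown arrays all lie below the control arrays.

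No other gene passed the test. Of 18916 genes, 1 was lower (Kdm1a) and 0 were higher by limma, with 1050 at an unadjusted p under 0.05, of which 722 were lower and 328 higher, where chance alone gives 946. With the replicate block 2014 genes had an unadjusted p under 0.05, of which 1488 were lower and 526 higher, and leaving out 1 array gave from 592 (without knockdown 2) to 1943 (without control 1). The authors' gene-level table, fitted the same way, gave 1 lower and 0 higher of its 23770 rows. Lower genes made up 68.8% of those at an unadjusted p under 0.05, 73.9% with the replicate block and 57.6% after cyclic loess, a renormalisation chosen after the data were seen. The groups did not overlap in 1165 genes with the knockdown below and 854 with it above, together 10.7% of genes, where chance gives 10%.

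Among the 11 lower genes named beside Kdm1a, none of which passed, Grsf1, an RNA-binding protein of mitochondria, had the smallest p, with a difference of -1.24 (SE 0.116, adjusted p = 0.0753). Grsf1 passed when dim genes were left out (12610 or 9458 genes tested) and with array weights. The others were Tmem59 (-1.44), Vta1 (-1.26), which acts in endosomal sorting, Arpc1a (-1.14), a subunit of the actin-nucleating Arp2/3 complex, the secreted matrix protein gene Thbs1 (-1.06), C1d (-1.03), Hint3 (-0.84), the vomeronasal receptor Vmn2r2 (-0.84), Nsfl1c (-0.82), a cofactor of the p97 ATPase, the EGR corepressor Nab1 (-0.81) and Clic1 (-0.79). Their adjusted p ran up to 0.647. The 12 higher genes had adjusted p from 0.647 to 0.714 and differences from 0.53 to 1.10, and 8 of them had a mean signal below the median of all genes, 5.40. They were Slc37a3 (1.10), a sugar phosphate transporter family member, D11Bhm181e (0.98), Dph3b-ps (0.82), Pglyrp2 (0.78), a peptidoglycan-binding amidase, the small GTPase gene Rab19 (0.72), Ezhip (0.69), an inhibitor of the PRC2 methyltransferase, the transcription factor gene Tcf21 (0.68), the linker histone gene H1f6 (0.54), Armcx3 (0.53) and the olfactory receptor genes Olfr486 (0.80), Olfr585 (0.73) and Olfr22-ps1 (0.59). Slc37a3 and Rab19 lie close together on chromosome 6, so their differences may not be independent. Olfactory and vomeronasal receptors are large families whose probes can pick up related transcripts.

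**Figure D2:**
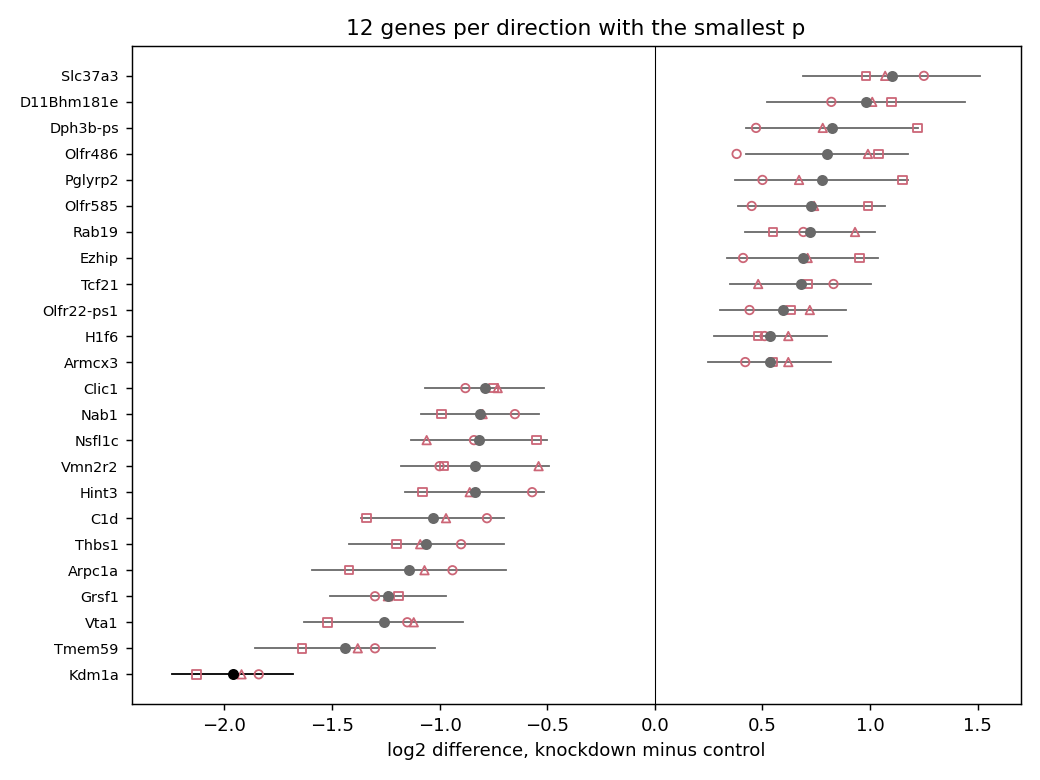
Log2 difference, knockdown minus control (x axis), of the 12 genes per direction with the smallest p. Filled points with lines give the fitted difference and 95% interval, black for Kdm1a, the gene that passed, and open symbols give arrays of the same number (circles 1, squares 2, triangles 3).

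Genes of cholesterol synthesis were lower as a group, with a median difference of -0.27 and all 17 measured members of 24 below 0 (camera adjusted p = 0.000161). This call was lost with an estimated correlation (adjusted p = 0.932) and with fry (adjusted p = 0.437). Sc5d, a late enzyme of the pathway, differed by -0.63 and Sqle, which makes squalene epoxide, by -0.47, and 0 members passed, also when adjusted over the list alone. Genes of oxidative phosphorylation had a median of -0.12 with 29 of 30 measured members below 0 (camera adjusted p = 0.0132), among them the complex I subunits Ndufb3 (-0.68) and Ndufv2 (-0.36). This call too was lost with an estimated correlation (adjusted p = 0.932) and with fry (adjusted p = 0.724), and no other list passed camera with either correlation or the directional fry. After cyclic loess the medians were -0.17 (camera adjusted p = 0.0502) and 0.01 (0.892), and after quantile normalization -0.17 (0.0517) and 0.01 (0.909), so both calls ended in each. The cholesterol call also ended without control 1 (0.0758). The oxidative phosphorylation call ended without control 2 (0.0804), control 3 (0.152), knockdown 1 (0.127) or knockdown 2 (0.0803), among the 12610 brighter genes (0.152) with the brightest probe set of each gene (0.0504), with the array class as a block (median -0.04, adjusted p = 0.195) and with array class and number-1 arrays as blocks (-0.08, 0.179). Within the 2 classes of arrays described below by upper quartile, the cholesterol medians were -0.40 and -0.20 and those of oxidative phosphorylation -0.01 and -0.09. Control 1 was the only control in the lower class, so class values mix with a difference of the number-1 arrays described below. With both blocks the cholesterol median was -0.18 (camera adjusted p = 0.000251, and 0.98 with an estimated correlation).

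**Figure D3:**
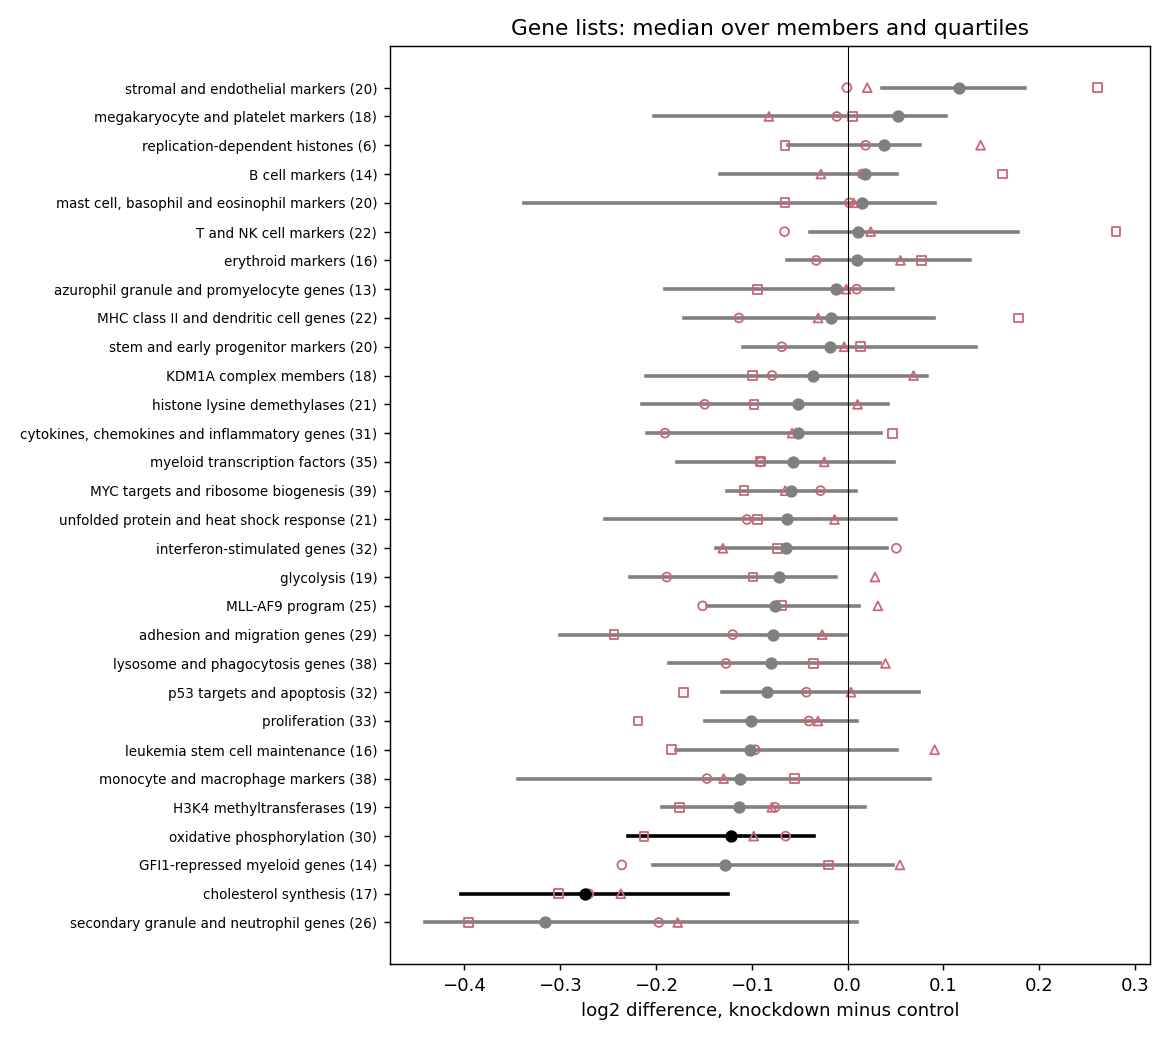
Median log2 difference, knockdown minus control (x axis), of the 30 gene lists, with the number of measured genes in parentheses. Filled points with bars give the median and quartiles over genes, black where camera passed, and open symbols the medians for arrays of the same number (circles 1, squares 2, triangles 3).

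Neutrophil and monocyte genes did not pass in the fit by group alone. The secondary granule and neutrophil list had a median of -0.32 with 19 of 26 members below 0 (camera adjusted p = 0.205), and its call appeared with the replicate block (adjusted p = 0.00152), where the adjusted p was 0.850 with an estimated correlation and 0.289 with fry. It also passed with the number-1 arrays as a block (0.000791) and with the array class as a block (median -0.42, adjusted p = 6.99e-05, and 0.798 with an estimated correlation there). The class block mixes with the difference of the number-1 arrays, described below. With both blocks together the median was -0.25 (camera adjusted p = 0.0008, and 0.98 with an estimated correlation). Without control 1 its median turned to 0.10 (camera adjusted p = 0.718), and it passed without control 2 (0.0256), control 3 (0.0011) or knockdown 1 (6.41e-06). Leaving out control 1 or knockdown 1 leaves a number-1 array in 1 group only, and this list had a median 0.88 higher in those arrays. Its medians for arrays of the same number were -0.20, -0.40 and -0.18, and within the array classes -0.66 and -0.23. Padi4, which citrullinates histones in granulocytes, differed by -0.33, and Cebpe, a factor of granule gene expression, by -0.43. Monocyte and macrophage markers had a median of -0.11 with 23 of 38 members below 0 (adjusted p = 0.472). This list passed without control 2 (0.0256), without knockdown 1 (0.0013) and with the array class as a block (median -0.24, adjusted p = 0.00411, and 0.798 with an estimated correlation there), and without control 1 its median was 0.04. With both blocks together its median was -0.10 and it did not pass (camera adjusted p = 0.0926). These markers too were higher in the number-1 arrays, by a median of 0.44. The C-type lectin gene Clec4a2, at -1.43, was the 1 member that passed when adjusted over the list alone, against 0 over all genes. Clec4a2 has close relatives whose transcripts its probes could share. Azurophil granule genes had a median of -0.01, myeloid transcription factors -0.06 and GFI1-repressed genes -0.13, with adjusted p of 0.851, 0.769 and 0.569.

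The leukemia program showed no change that passed. The MLL-AF9 program list had a median of -0.08 with 18 of 25 members below 0 (camera adjusted p = 0.398), leukemia stem cell maintenance genes -0.10 (0.486) and stem and early progenitor markers -0.02 (0.804), where camera's direction was up. Hoxa9 differed by -0.20, Meis1 by -0.17, Myb by -0.09 and Myc by 0.03. Among the partners of Kdm1a, Hdac2 differed by -0.65 (adjusted p = 0.699), Rcor1 by -0.24 and Gfi1 by 0.08. In the KDM1A complex list, 2 members (Kdm1a and Hdac2) were lower when adjusted over the list alone, and in the histone demethylase list 1 (Kdm1a), against 1 over all genes in each. Fry's test for change in either direction passed for both lists (adjusted p = 0.000776 each), and without Kdm1a its unadjusted p was 0.0563 and 0.0497. Their medians were -0.04 and -0.05 (adjusted p = 0.41 and 0.267), and that of the H3K4 methyltransferases -0.11 (0.346).

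Markers of other cell types had medians close to 0. These were 0.12 for stromal and endothelial markers (16 of 20 above 0), 0.05 for megakaryocyte and platelet markers, 0.02 for B cells, 0.01 for T and NK cells, 0.01 for erythroid cells, 0.01 for mast cells, basophils and eosinophils, and -0.02 for MHC class II and dendritic cell genes. None passed in the fit by group alone, and the stromal list had a camera adjusted p of 0.137 there and 0.0498 with the replicate block, where the adjusted p was 0.850 with an estimated correlation and 0.450 with fry. The stromal list also passed, higher, without knockdown 3 (0.0287), and the T and NK cell list, higher, without control 1 (0.0237). Thbs1 (-1.06) and Ppbp (-0.83), the gene of a platelet chemokine, were the 2 megakaryocyte and platelet members lower when adjusted over the list alone, against 0 over all genes.

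Of the remaining lists, proliferation genes had a median of -0.10 with 24 of 33 members below 0 (camera adjusted p = 0.381), MYC targets and ribosome biogenesis -0.06 (0.695), p53 targets and apoptosis -0.08 (0.537), inflammatory genes -0.05 (0.918), lysosome and phagocytosis genes -0.08 (0.483), adhesion and migration genes -0.08 (0.471), glycolysis -0.07 (0.346), the unfolded protein and heat shock response -0.06 (0.471) and replication-dependent histones 0.04 (0.918). Interferon-stimulated genes had a median of -0.06 (0.851), which turned to 0.19 with the array class as a block (adjusted p = 0.0457, and 0.798 with an estimated correlation there) and was -0.34 without control 1 (0.0291). Leaving out 1 array gave calls of lower adhesion and migration genes without knockdown 1 (0.00553), lower glycolysis genes without control 3 (0.0163) and lower MYC targets without control 1 (0.0358). Without control 1 or knockdown 1, a number-1 array remains in 1 group only, so lists that differ in those arrays shift. Number 1 minus the others had a median of 0.42 for adhesion and migration genes, -0.45 for MYC targets and -0.85 for interferon-stimulated genes. Among the members of these lists, Pdia6, a protein disulfide isomerase, differed by -0.49, the ribosome assembly gene Rrs1 by 0.54 and the glycolytic gene Eno1 by -0.71, and none passed. Eno1 had only 2 probe sets, with means of 4.66 in the controls and 3.95 in the knockdown. Both means lay below the median of all genes, 5.40.

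The arrays differed in their spread of signal in a way the groups follow only in part. The upper quartile over genes was 6.93 in control 1, 6.83 in knockdown 1 and 6.89 in knockdown 2, and 7.13 in control 2, 7.16 in control 3 and 7.11 in knockdown 3. The lower class thus held 1 control and 2 knockdown arrays, and each knockdown array lay below the control of the same number. Over 10 bins of genes ordered by brightness, the median difference between knockdown and control ran from 0.06 in the fourth to -0.14 in the ninth, and in the arrays numbered 2, which fall in different classes, from 0.18 to -0.27. In the arrays numbered 1 and 3, where both arrays of a number fall in the same class, the ninth bin lay at -0.096 and -0.071. With the class as a block Kdm1a differed by -1.93 (limma adjusted p = 0.0301), and within the classes by -1.96 and -1.91.

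**Figure D4:**
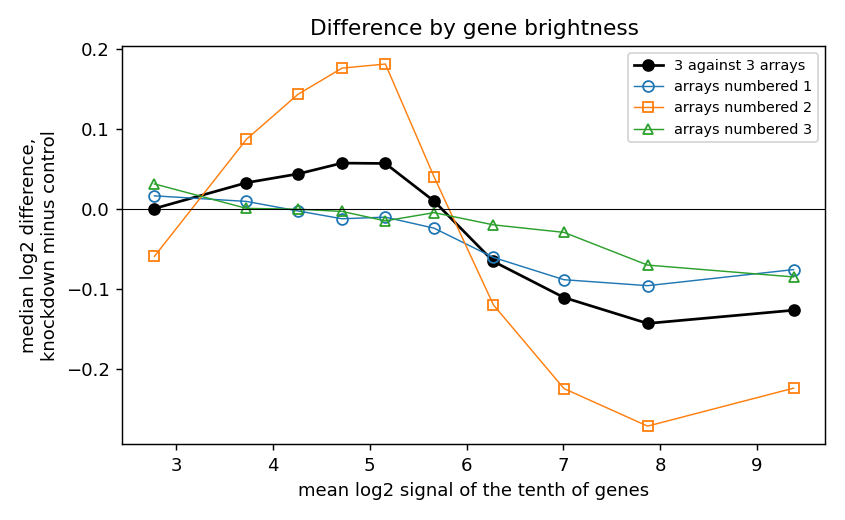
Median log2 difference, knockdown minus control (y axis), of 10 bins of genes ordered by brightness, against their mean log2 signal (x axis), for all arrays (filled) and for arrays of the same number (open). The ninth bin lies at -0.14 over all arrays and at -0.27 in the arrays numbered 2.

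At the level of single probe sets, 0 of 267824 passed by limma, with 14208 at an unadjusted p under 0.05 and a smallest adjusted p of 0.408. With an intensity trend in the prior variance 11 passed, all of them lower and all belonging to Kdm1a or Grsf1. The probe sets of a gene changed unequally in 11 of 17840 genes by diffSplice's F test and in 37 with the replicate block, and 1078 had an unadjusted p under 0.05. The Simes test of the same fit, which asks whether any single probe set departs from its gene, passed for 123 genes. The genes that passed the F test, named for that reason, were Kdm1a, Grsf1, Pstpip2, Trip12, Grk5, Tmem59, Prom1, Hdac2, Cdc40, Hivep1 and Rab3d. In Pstpip2, an adaptor protein of the myeloid lineage, probe sets ranged from -2.15 to 0.50, in Hdac2 from -1.84 to 0.28 and in Prom1, a progenitor surface marker, from -1.39 to 1.69. The number was 74 without control 1, 2 without control 2, 2 without control 3, 18 without knockdown 1, 3 without knockdown 2 and 18 without knockdown 3. It was 7 without the dimmer probe sets, of which 4 were among the 11 named. Kdm1a then had an adjusted p of 0.0245 in the F test, against 7.39e-12 with all probe sets.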

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

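Cyclic loess, the brightest probe set, the authors' gene table, the blocks for array classes and number-1 arrays, the lists without Kdm1a, matched random lists, estimated correlations within blocked fits and every alternative for unequal probe sets were chosen after the data were seen, and the others given here before the data were examined. Averaging rows in place of the brightest row was not run as an alternative, because the mean became the value reported. Leaving out each array in turn gave 0 to 1 changed genes, 0 to 1 lower, a Kdm1a difference of -2.001 to -1.885 with adjusted p of 0.037 to 0.112, 1 to 4 gene lists and 2 to 74 genes with unequal probe sets. Fewer arrays leave fewer degrees of freedom. The count of changed genes was 2, both lower, with dim genes left out (12610 or 9458 genes tested), with array weights and at an adjusted p under 0.10. It was 22, with 4 higher and 18 lower, at an unadjusted p under 0.01 with an absolute difference of at least 1. It was 0, with 0 lower, with the brightest probe set, where Kdm1a differed by -2.50 (adjusted p = 0.0545), and with array class and number-1 arrays as blocks together, where it differed by -1.879 (0.0642); the cause was not tested.

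The replicate block, which uses the pairing by number, gave 4 gene lists and 37 genes with unequal probe sets, and it changed no other call. The number of lists past the threshold was 0 after quantile normalization, 0 after cyclic loess, 0 with an estimated correlation, 0 with fry, 1 among the 12610 brighter genes, 1 with the brightest probe set and 4 with the array class as a block. The oxidative phosphorylation median became 0.0092 after quantile normalization (adjusted p = 0.909) and 0.0101 after cyclic loess (0.892), 2 methods that by construction remove a trend with brightness. The interferon list became 0.19 with the array class as a block (adjusted p = 0.0457), a block that mixes with the difference of the number-1 arrays, and it did not pass with both blocks together. Without the dimmer probe sets (133912 probe sets and 13142 genes tested) 7 genes had unequal probe sets, and only 4 of these were among the 11. The adjusted p of Kdm1a in the F test rose from 7.39e-12 to 0.0245 there. The unequal change thus depended in part on dim probe sets. With an intensity trend 11 probe sets passed, all lower and all of Kdm1a or Grsf1. Among 1581 values of the other named genes under the alternatives, 1550 kept their direction and side of the threshold, 28 of 15 genes that had not passed changed sign and 3 passed newly. Among 480 list values, 352 kept both, 93 of lists that had not passed changed sign, 17 passed newly, 15 no longer passed and 3 reversed. Dim genes lie close to background, where differences between arrays carry little information.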

Other observations

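Tests of dividing cells, of other cells in the number-1 samples and of another animal were chosen after the result was seen. The matched random lists, estimated correlations within blocked fits, cyclic loess and the blocks for array class and number-1 arrays were added after the data were seen; what cyclic loess, the class block and the matched lists of cholesterol synthesis and oxidative phosphorylation would show was written before their results, and nothing was written beforehand for the others. For the shares of lower genes, the rule that the exact binomial interval must clear 60% was added after both values were seen; before it, the cyclic loess share had been read as meeting the bound and the class share as exceeding it.

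The arrays numbered 1, in both groups, stood apart from the other 4. Xlr was at 1.96 in control 1 and 1.99 in knockdown 1 against 7.18 to 7.78 elsewhere, and the stem cell factor receptor Kit at 5.37 and 5.08 against 7.37 to 7.58. Lpl, lipoprotein lipase, was at 9.03 and 8.78 against 5.05 to 5.84, and the neutrophil granule gene Ltf at 7.10 and 7.30 against 4.41 to 4.63. Over lists, number 1 minus the others had a median of 0.88 for secondary granule and neutrophil genes (5 of 26 members lower), 0.44 for monocyte markers, -0.85 for interferon-stimulated genes (29 of 32 lower) and -0.45 for MYC targets (35 of 39 lower). These genes were named after their values were seen.

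Between knockdown and control, the secondary granule and neutrophil list had a lower median than every one of 10000 random lists matched on mean expression (0.01%, the smallest share they can give; 0.006 as a p adjusted over 30 lists). With array class and number-1 arrays as blocks its median was -0.25 (camera adjusted p = 0.0008), but the adjusted p there was 0.98 with an estimated correlation and 0.105 with fry, and it missed the threshold in the fit by group alone. Its median turned to 0.10 without control 1, a fit that leaves knockdown 1 as the only number-1 array. Random lists ignore the correlation between its members, which was 0.314 in the fit by group alone. With both blocks the estimated correlation was -0.039. The unadjusted p there was 0.0457 by camera with this correlation and 0.0035 by fry, and neither passed when adjusted over the 30 lists.

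Lower cholesterol synthesis and oxidative phosphorylation genes were set against a shift that depends on brightness, against the array classes and against fewer dividing cells. For cholesterol synthesis, 0.24% of matched random lists had a median as low (0.072 adjusted over 30 lists). Random lists ignore the correlation between its members, 0.28, so this share may be too small. The median was -0.28 with the class as a block (camera adjusted p = 1.12e-05, but 0.798 with an estimated correlation there). That block mixes with the difference of the number-1 arrays, and with both blocks the median was -0.18 (0.000251, but 0.98 with an estimated correlation). These values argue against brightness or the array classes as the whole cause only if its members are little correlated. The proliferation median lay 0.173 above the cholesterol median (bootstrap interval 0.0279 to 0.306). This interval is over genes and ignores their correlation and the spread between samples, so it cannot decide on fewer dividing cells. Cyclic loess took the cholesterol median from -0.27 to -0.17 and the call ended at a camera adjusted p of 0.0502, while matched lists had a median of -0.11, so brightness may account for part of the difference. For oxidative phosphorylation, 39.3% of matched lists were as low and the adjusted p was 0.195 with the class as a block, so a candidate explanation is the array classes with their brightness trend. An effect of the knockdown on sterol synthesis stays open for the former, as an untested hypothesis.

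Lower genes outnumbered higher ones at an unadjusted p under 0.05, with 722 lower and 328 higher (68.8% lower). After cyclic loess there were 611 lower and 449 higher (57.6%, exact binomial interval 54.6 to 60.6), with the array class as a block 708 and 428 (62.3%, 59.4 to 65.2), and with the replicate block 1488 and 526 (73.9%). Loess recentres the differences at every brightness and so moves the share by construction, and with the class block the share fell mostly because more genes were higher. Neither share decides whether brightness, array class or the knockdown lies behind the excess, and these cannot be told apart here.

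For the 13 genes at least 2 lower in the number-1 arrays, admixed cells without the MLL-AF9 program would have to dilute that program alike. Its median lay 0.0582 above that of the other arrays (interval -0.156 to 0.208), which argues against such cells. Admixed cells that carry the program are not covered by this test and stay open. Pbx3, a member of the list, was itself among the 13 genes, at 5.24 in control 1 and 5.44 in knockdown 1 against 8.07 to 8.32 elsewhere. For the 11 genes at least 2 higher, admixed cells of any kind stay open. The neutrophil list lay 0.878 higher, which a small share of neutrophils could bring and a change in the leukemia cells could bring too. Another animal or a shared day of preparation behind both number-1 samples also stays open, since no label ties a sample to an animal. The correlation of 0.625 between the deviations of control 1 and knockdown 1 only restates that both arrays stand apart.

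With 3 against 3 arrays there are 10 splits, too few for a share under 0.05. The real split gave 1 changed gene and 1 lower gene, the highest other 1 and 1, and 2 of the 10 splits gave as many in each case. For gene lists 7 splits gave as many as the real 2, with up to 12, and for unequal probe sets 2 splits gave as many as the real 11, with up to 830. The split of control 1, knockdown 1 and knockdown 2 from the rest, which follows the upper quartiles, gave 830 genes with unequal probe sets, 10 lists and 4345 genes at an unadjusted p under 0.05, which points to a structure of the samples. Of the splits that part all 3 pairs as the real one does, the others gave 0 changed genes and up to 2 lists.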
